A study of Mus musculus with 18 samples.

How the data were processed

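RNA was sequenced from 18 Pten-null prostate tumours of FVB mice, with 1 library from each animal. The labels put 5 animals in the vehicle group (1% polysorbate 80), 5 in the AZD2014 group (15 mg/kg/day), 4 in the castration group (castrated and given vehicle) and 4 in the castration + AZD2014 group (castrated and given 15 mg/kg/day). AZD2014 is an ATP-competitive inhibitor of the mTOR kinase, which acts in both mTOR complexes. No more than 4 hours passed between the final dose and removal of the tumour. The labels give ages of 8.6 to 13.6 months at collection and name no litter, day or sequencing batch.

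The authors deposited raw read counts per Ensembl gene, 1 table for each library, with no normalization. Per the labels, 50 bp single-end Illumina HiSeq reads were aligned with TopHat 2.0.4 to the mouse genome (GRCm38, mm10) and counted with HTSeq, whose version and settings were not stated. The authors' own normalization and test (DESeq 1.10.1) are not part of the deposited tables. Each table held 39179 gene identifiers and 5 summary lines of the counting program, which were set aside before scaling. Symbols, biotypes and mm10 coordinates came from GENCODE release M21, which named 37607 of the identifiers (96.0%), and the identifiers without a name held at most 0.24% of a library's counts.

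Gene totals ran from 4001238 to 8457490 counts per library. Group means were 7864278 counts in vehicle, 7015993 in AZD2014, 5746917 in castration and 6931608 in castration + AZD2014. Reads that mapped to several places made up 26.51% to 34.23% of all lines counted and reads outside genes 2.66% to 6.06%. Between replicates of a group the variance of counts was on average 9.29 to 165 times the counting variance over 32 pairs. This is a mean over genes in which abundant genes weigh most, so it does not show what depth limits for genes of few counts. Intervals and limits given for counts near 0 pool the counts of a group's animals, so they leave out the spread between animals. They cover counting error only, and the reads carry no molecular identifiers by which copies could be told apart.

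Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on the 4 groups with its minimum count of 10, which left 13777 genes, and libraries were scaled by TMM factors. All 18 libraries entered 1 quasi-likelihood fit with robust shrinkage and a mean for each group. The biological coefficient of variation was 26.5%. Each comparison and the interaction between castration and AZD2014 were tested with the two-sided F test of that fit, and p-values were adjusted by Benjamini-Hochberg over all genes tested within a comparison. A gene was called at an adjusted p below 0.05. Errors of log2 fold changes are standard errors from the same test. Levels are given as CPM on TMM-scaled library sizes, with the SD between animals.

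A total of 31 lists of pathway genes and cell type markers were tested with camera (limma 3.58.1) at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 31 lists within a comparison. The same test with a correlation estimated from the data stands beside it. Of 572 list members, 571 matched a gene identifier. A list score is the mean over tested members of log2 CPM (prior count 2) centred on each gene's mean over the 18 libraries. The groups, comparisons, tests, threshold, lists and the rule for naming genes were fixed before the data were examined. Under that rule, the text could name for each comparison the 6 called protein-coding genes with the largest rise and the 6 with the largest fall, given a mean of at least 1 CPM and no overlap between the groups. Without calls it took the 3 higher and 3 lower genes of smallest p. It also took up to 4 members of each list described, 6 genes of smallest p for the interaction, and always Pten, Ar, Nr3c1, Mtor, Rptor and Rictor.

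Results were recomputed with DESeq2 1.42.0 (genes only, not lists), with its size factors in edgeR, with no filter and with a stricter filter (1 CPM in 4 libraries), with only the groups compared (not for the interaction), without robust shrinkage, with limma voom and quality weights, with replicate number as a block, with age as a covariate, and without each of the 18 libraries. After the data were examined, fits without vehicle libraries 1 and 5, fits thinned to lower depth and a fit with macrophage and T cell scores as covariates were added. A test that picked genes in part of the intact libraries and held out the rest was added as well. Replicate numbers run from the oldest to the youngest animal within a group and were not treated as pairs. Residuals of the 25 pairs with the same number correlated at only -0.40 to 0.35. Vehicle and AZD2014 animals of the same number were close in age (13.6 and 13.5 months for number 1, 8.7 each for number 5). Castrated animals were not always (12 months in vehicle and 8.7 in castration for number 3). The correlations over all pairs therefore cannot exclude matching by age in part of the groups. Other splits of the libraries were drawn, at most 100 for each comparison. The test was also tested on simulated data with the depth and spread of these libraries, where it recovered 49 to 66 of 100 genes changed 2-fold and 85 to 92 of 100 changed 4-fold in the 5 group comparisons. For the interaction it recovered 35 and 74 of 100. No library was left out of the values reported as such.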

Results

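Gene expression was measured by RNA sequencing in prostate tumours of 18 mice, given by the labels as null for Pten, the phosphatase that opposes PI3K signalling. The animals formed 4 groups: vehicle (n = 5), AZD2014 (n = 5), castration (n = 4) and castration + AZD2014 (n = 4). Gene totals were 7311934 to 8457490 counts in the vehicle libraries, 4877760 to 8111371 with AZD2014, 4001238 to 7044483 after castration and 6782694 to 7004289 after castration + AZD2014. The 8 seminal vesicle marker genes held 12.1% of the counts of vehicle library 1 (95% Wilson interval 12.06% to 12.10%) and 13.7% of those of vehicle library 5 (13.69% to 13.74%). They held 1.01% in castration + AZD2014 library 3 (0.9992% to 1.014%), and at most 0.0634% (0.06099% to 0.06592%, castration library 1) in the other 15 libraries. On the first principal component, which held 34.4% of the variance, vehicle library 3 lay at 36.3, among the 8 castrated libraries (16 to 59.2), while the other 4 vehicle libraries lay at -34.8 to -17.4. Vehicle library 3 had 176 CPM of the secretory gene 5430419D17Rik, against at most 5.69 CPM in the castrated libraries. It had 113 CPM of Hist1h1c, against at least 719 CPM in the AZD2014 libraries. Both genes were named for groups that did not overlap, so the side on which library 3 lay was fixed in advance. Its prostate secretory list score was -0.25, the lowest of the intact libraries (the others 0.11 to 3.27). The castrated libraries scored -2.18 to -0.94.

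**Figure D1:**
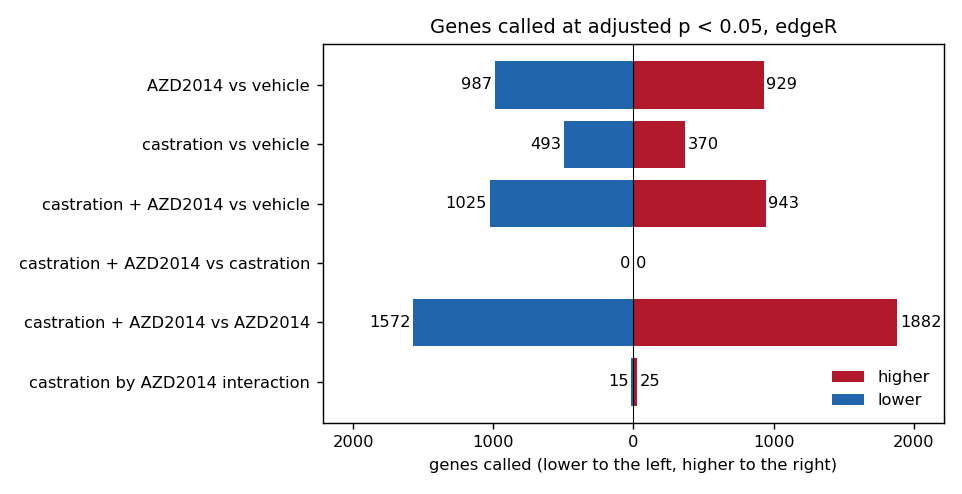
Number of genes called lower (blue, to the left) and higher (red, to the right) at an adjusted p below 0.05 in each comparison and in the interaction, by edgeR. AZD2014 changed 1916 genes in intact animals and 0 in castrated animals by this test (1522 had an unadjusted p below 0.05, and DESeq2 called 105 and voom 121), and the interaction itself passed for 40 genes.

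AZD2014 against vehicle asked what the mTOR kinase inhibitor changed in tumours of intact animals. In the AZD2014 tumours 929 genes were higher and 987 lower, 414 of these calls by more than 2-fold. Named by size here and below are called protein-coding genes of at least 1 CPM whose groups did not overlap. The largest rises among them were in linker and core histone genes: Hist1h1d (ENSMUSG00000052565, chromosome 13, 23553262 to 23560686) rose from 3.34 ± 2.14 CPM (SD, n = 5) to 39.7 ± 16.1 CPM (SD, n = 5), a log2 fold change of 3.59 ± 0.36 (SE, adjusted p = 1.96e-05). The abundant linker histone gene Hist1h1c rose from 166 ± 36.3 to 899 ± 257 CPM (SD, n = 5 each; log2 2.43 ± 0.19, adjusted p = 1.26e-06). Cell cycle genes were among those that fell, with Cdk1, the kinase that drives entry into mitosis, going from 13.8 ± 3.36 to 3.46 ± 0.886 CPM (SD, n = 5 each; log2 -1.98 ± 0.39, adjusted p = 0.00368). Each of these genes was higher, or lower, in 5 of 5 AZD2014 libraries than in any vehicle library. The naming rule required this of the histone genes but not of Cdk1.

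Among the other genes with the largest rises, Hist1h1e gained 3.43, Hist1h2be 3.29, Hist1h2bg 2.61 and Rgs9bp, an anchor of a regulator of G protein signalling, 2.58 on the log2 scale. Among genes whose groups did not overlap, the largest falls were in Lpo (lactoperoxidase), Krt13, Pfkfb3, Cdkn3, Adm2 and Nuf2, a kinetochore gene. Seminal vesicle genes, high in vehicle libraries 1 and 5, fell further (median -10.15, 5 of 6 called, 6 adjusted over the list alone), but did not pass as a list (adjusted p = 0.148). Krt13 changed by -3.92, Pfkfb3, an activator of glycolysis, by -2.90, Cdkn3 by -2.66, Adm2 by -2.57 and Nuf2 by -2.51. Lpo counts fell from 1952 in the vehicle group to 1 in the AZD2014 group, a ratio of 1870 (counting interval 335 to 73800), but vehicle library 5 alone held 300 CPM and the others 0.264 to 2.30 CPM. The call of Lpo ended without AZD2014 library 2 (log2 -11.73 against -10.35), and its change was -4.79 without vehicle library 5. Single vehicle libraries also carried much of the fall of Pfkfb3 (-1.60 without vehicle library 5) and of Krt13 (-2.52 without vehicle library 3).

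Of 31 measured cell cycle and DNA replication genes, 19 fell, none rose and 12 did not pass, with a median log2 fold change of -1.51 (26 fell when adjusted over the list alone; camera adjusted p = 6.48e-16, but 0.373 with an estimated correlation). The scores of all 5 AZD2014 libraries lay below those of all 5 vehicle libraries. Ccne1 and E2f1, which act at the entry into S phase, changed by -1.88 and -1.75, and Pcna, the DNA polymerase clamp, by -0.56. Sterol synthesis and uptake genes fell in 10 of 23 cases (median -0.57, 14 adjusted over the list alone, adjusted p = 3.28e-10, but 0.251 with an estimated correlation), with Msmo1 at -1.25 ± 0.13, Dhcr24 at -1.19 ± 0.14, and Insig1 and Fdps at -1.03 each. FoxO targets and receptor genes that PI3K-mTOR inhibition is known to release rose in 8 of 21 cases (median 0.41, 10 higher and 1 lower adjusted over the list alone, adjusted p = 4.25e-06, but 0.373 with an estimated correlation). Examples were Fbxo32, a ubiquitin ligase of muscle wasting, at 1.17 ± 0.15, Txnip at 0.99, the cell cycle inhibitor Cdkn1b at 0.63 and Pik3ip1, an inhibitor of PI3K, at 0.62.

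Of 23 glycolysis and HIF target genes, 7 fell (median -0.46, 12 adjusted over the list alone, adjusted p = 1.01e-05, but 0.704 with an estimated correlation), with the lactate carrier Slc16a3 at -2.40, Ankrd37 at -1.89 and the glucose carrier Slc2a1 at -1.09. The glycolysis median was -0.28 without vehicle library 2, and the scores of the groups overlapped (-0.67 to -0.22 against -0.45 to 0.90). ATF4 targets and amino acid genes fell in 9 of 27 cases (median -0.36, 11 lower and 1 higher adjusted over the list alone, adjusted p = 2.48e-05, but 0.568 with an estimated correlation), including Slc1a4 at -1.25, Ddit4, an inhibitor of mTORC1, at -1.04, and the alanyl-tRNA synthetase gene Aars at -0.78. In ribosome biogenesis 8 of 28 genes fell and 1 rose (median -0.25, 11 lower and 1 higher adjusted over the list alone, adjusted p = 3.09e-05, but 0.373 with an estimated correlation), with Nolc1 at -0.92 ± 0.08, Heatr1 at -0.86 and Gnl3 at -0.79. Basal epithelium markers fell in 5 of 11 cases (median -1.5, 6 adjusted over the list alone, adjusted p = 0.00011, but 0.704 with an estimated correlation), with Krt17 at -2.03 and Krt5 at -1.66, and 4 of 5 AZD2014 libraries had a score below the vehicle mean. Krt5 was no longer called with only the groups compared (-1.67). Fibroblast and matrix genes passed as a list (median -1.48, adjusted p = 0.016, but 0.84 with an estimated correlation) with 0 of 22 members called by edgeR. Tnc (-2 ± 0.74) and Sparc (-1.24 ± 0.46) were its members of smallest p, both called by DESeq2, and Tnc was also called without vehicle library 4 (-2.28), while without vehicle library 3 they stood at -0.60 and -0.67. That list's call ended without vehicle library 3 (median -0.46), vehicle library 5 (-1.5) or AZD2014 library 5 (-1.41), and its median was 0.09 with voom.

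Pten transcripts were higher with AZD2014 (60.1 ± 7.45 against 87.6 ± 6.45 CPM, SD, n = 5 each; log2 0.54 ± 0.13, adjusted p = 0.00944), as were those of the androgen receptor gene Ar (0.73 ± 0.18, adjusted p = 0.0133), and neither passed without vehicle libraries 1 and 5 (0.50 and 0.72). Pten counts are over the whole gene and do not show whether a part of it is deleted. Mtor (0.09), Rptor (0.15), Rictor (0.52) and Nr3c1, the glucocorticoid receptor gene (0.08), did not pass. Groups did not overlap for 1711 genes (12.4%, where chance gives 0.79%). Without vehicle libraries 1 and 5 the count of 1916 was 1263, with 486 higher and 777 lower against 929 and 987.

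Castration against vehicle asked what the removal of testicular androgen changed in tumours without the drug. Genes of prostate secretory proteins and part of the androgen receptor targets were among those that fell, and macrophage and part of the T cell markers among those that rose. Nkx3-1, an androgen-regulated transcription factor of the prostate epithelium (ENSMUSG00000022061, chromosome 14, 69190638 to 69194662), fell from 8.29 ± 4.42 CPM (SD, n = 5) to 0.287 ± 0.225 CPM (SD, n = 4), a log2 fold change of -4.74 ± 0.72 (SE, adjusted p = 0.000761). C1qb, a complement gene of macrophages, rose from 77.5 ± 22.4 CPM (SD, n = 5) to 201 ± 31.3 CPM (SD, n = 4; log2 1.38 ± 0.17, adjusted p = 0.000206). In total 370 genes were higher and 493 lower, 400 of them by more than 2-fold.

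Among genes whose groups did not overlap, the largest rises were in Cdhr1, a cadherin-related gene, from 4.74 ± 4.82 to 214 ± 85.2 CPM (SD, n = 5 and 4; log2 5.47 ± 0.66, adjusted p = 0.000226), Pnliprp1 (4.12), Ccdc190 (3.87), Rgs4 (3.52), the B cell chemokine gene Cxcl13 (3.48) and BC100530 (2.94). The largest falls among such genes were in Msmb (-8.27), which encodes a secreted prostate protein, 5430419D17Rik (-7.73 ± 0.59, adjusted p = 4.02e-06), Mup20 (-7.53), Abo (-7.36), Spink5 (-6.75) and 9530002B09Rik (-6.29). For all 12 genes the ranges of both groups were separate, as the rule for naming them required. Mup20 was no longer called with voom (-7.26), and Pnliprp1 was no longer called without castration library 3 (3.84). Ccdc190 stood at 6.41 without vehicle library 3.

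Of 10 measured secretory genes of the prostate lobes, 5 fell and none rose (median -4.06, 9 lower adjusted over the list alone, adjusted p = 2.43e-08, and 0.0385 with an estimated correlation). Sbp counts fell from 114 to 1, a ratio of 73.7 (counting interval 13.0 to 2940), Azgp1 changed by -2.83 and Pigr, the receptor that carries polymeric immunoglobulin, by -1.05, though Azgp1 and Pigr did not pass with only the groups compared (-2.82 and -1.03). The list's median was the same with genes of 0 to 3 counts in a group set at their bound, but -2.30 without vehicle library 1 and -1.55 without vehicle libraries 1 and 5. Androgen receptor targets outside the secretory list fell in 5 of 24 cases (median -0.32, 7 adjusted over the list alone, adjusted p = 0.00049, and 0.0385 with an estimated correlation), among them Fkbp5, a co-chaperone gene, at -1.62 ± 0.28 and Stk39 at -0.99 ± 0.13. Macrophage markers rose in 8 of 11 cases (median 1.39, 9 adjusted over the list alone, adjusted p = 1.74e-20, and 0.0188 with an estimated correlation), with Ms4a7 at 1.5, C1qc at 1.43 and C1qa at 1.39. The 4 castration libraries lay beyond all 5 vehicle libraries in each of these 3 list scores.

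T and NK cell markers rose in 5 of 11 cases (median 1.31, 11 adjusted over the list alone, adjusted p = 3.95e-09, but 0.13 with an estimated correlation), with the T cell receptor chains Cd3e at 1.78 and Cd3g at 1.58. Cd3e did not pass without vehicle libraries 1 and 5 (1.56). Sterol synthesis genes fell in 4 of 23 cases and rose in 2 (median -0.40, 11 lower and 2 higher adjusted over the list alone, adjusted p = 2.19e-06, but 0.195 with an estimated correlation), with Insig1 at -1.01 and Dhcr24 at -0.82. Smooth muscle genes fell in 3 of 10 cases (median -3.49, 9 adjusted over the list alone, adjusted p = 0.000625), a call that ended with an estimated correlation (adjusted p = 0.607) and with voom (median -1.30), and Synm (-2.56) did not pass with only the groups compared (-2.55). Without vehicle library 5, whose smooth muscle score was 4.29 against -1.12 to 0.98 in the other vehicle libraries, the median was -1.59 and Synm stood at -1.65. The inflammatory (median 0.79, 1 of 20 rose, 2 adjusted over the list alone), basal epithelium (1.07, 0 of 11, 4 adjusted over the list alone) and neutrophil lists (1.31, 0 of 8) passed as higher, but not without vehicle libraries 1 and 5 (0.55, 0.63 and 0.74), nor with an estimated correlation (adjusted p = 0.598, 0.607 and 0.607). Without castration library 1 the inflammatory median was 0.38 and the neutrophil median 0.75, and without vehicle library 3 the neutrophil median was 2.21. Pten (-0.01), Ar (0.22), Nr3c1 (0.16), Mtor (-0.07), Rptor (-0.03) and Rictor (0.13) did not pass.

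In the same comparison 1009 genes had groups that did not overlap (7.3%, where chance gives 1.59%). The count of 863 genes was 490 without vehicle library 1, 1598 without vehicle library 3, 502 without vehicle library 4, 407 without castration library 3, 434 without vehicle libraries 1 and 5, and 363 with only the groups compared.

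Castration + AZD2014 against vehicle asked what the combined treatment changed. Most interferon response and macrophage genes rose, and most prostate secretory and sterol synthesis genes fell. The interferon list had a median log2 fold change of 2.28, with 23 of 25 genes higher and none lower (24 adjusted over the list alone, adjusted p = 5.36e-20, but 0.184 with an estimated correlation). Tap1, the peptide carrier of antigen presentation (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225), rose from 49.4 ± 10 CPM (SD, n = 5) to 140 ± 55.3 CPM (SD, n = 4), a log2 fold change of 1.5 ± 0.23 (SE, adjusted p = 0.000551). The macrophage lysozyme gene Lyz2 rose from 155 ± 40.2 to 731 ± 110 CPM (SD, n = 5 and 4; log2 2.23 ± 0.25, adjusted p = 8.67e-05).

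A total of 943 genes were higher and 1025 lower, 783 by more than 2-fold. Cdhr1 (5.36), the collagenase gene Mmp13 (4.72), Ccdc190 (3.98), Slfn4 (3.92), Ms4a4c (3.87) and Slfn1 (3.53) had the largest rises among genes whose groups did not overlap. The largest falls among these were in genes at or near 0 after the combined treatment. With 0 counts over the group, 9530002B09Rik was at least 215-fold lower and Sbp at least 31.2-fold lower against a floor of 3 counts over the group, and Msmb (-8.60), Mup20 (-8.37), Spink5 (-7.60) and 5430419D17Rik (-7.32) followed. Ccdc190 stood at 6.51 without vehicle library 3. Slfn4 was not called without vehicle libraries 1 and 5 (3.52), and Msmb (-8.36), Mup20 (-8.10) and Spink5 (-7.66) were not called with voom.

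Other interferon genes that rose were Gbp2 (2.63), Bst2 (2.20) and Irf1 (0.73). Macrophage markers rose in 10 of 11 cases (median 1.32, 10 adjusted over the list alone, adjusted p = 1.78e-17, and 0.0394 with an estimated correlation), with C1qb at 1.33. Prostate secretory genes fell in 7 of 10 cases (median -3.78, also at the bound, 7 adjusted over the list alone, adjusted p = 3.85e-08, but 0.0705 with an estimated correlation), with Azgp1 at -3.64. Androgen receptor targets fell in 8 of 24 cases (median -0.25, 8 lower and 1 higher adjusted over the list alone, adjusted p = 0.00175, but 0.0728 with an estimated correlation), with Nkx3-1 at -3.61 and Stk39 at -1.10. Sterol synthesis genes fell in 13 of 23 cases (median -0.70, 17 lower and 2 higher adjusted over the list alone, adjusted p = 7.82e-11, but 0.0705 with an estimated correlation), with Insig1 at -1.69, Dhcr24 at -1.21 and Msmo1 at -0.87. In all of these 5 list scores the 4 castration + AZD2014 libraries lay beyond the 5 vehicle libraries.

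Oxidative phosphorylation genes fell in 10 of 35 cases (median -0.51, 31 adjusted over the list alone, adjusted p = 7.82e-11, but 0.384 with an estimated correlation), with Ndufa1 at -1.48. Scores of castration + AZD2014 libraries 1 and 3 (-0.61 and -0.68) lay below all vehicle libraries (-0.24 to 0.37), and those of libraries 2 and 4 (-0.10 and -0.09) within their range. Uqcrfs1 (-0.55), also called, did not pass without castration + AZD2014 library 1 (-0.47) or 3 (-0.48), without vehicle libraries 1 and 5 (-0.48) or with only the groups compared (-0.54). ATF4 and amino acid genes fell in 11 of 27 cases (median -0.40, 15 lower and 2 higher adjusted over the list alone, adjusted p = 4.23e-05, but 0.384 with an estimated correlation), with the mitochondrial folate enzyme gene Mthfd2 at -1.83, Pycr1 at -1.79 and Ddit4 at -1.11. T and NK markers rose in 5 of 11 cases (median 1.04, 8 adjusted over the list alone, adjusted p = 4.73e-05, but 0.384 with an estimated correlation), with granzyme B (Gzmb) at 2.23 and Cd3e at 1.71. FoxO targets rose in 7 of 21 cases and fell in 1 (median 0.28, 7 and 1 adjusted over the list alone, adjusted p = 0.00219, but 0.384 with an estimated correlation), with the pro-apoptotic Bcl2l11 at 0.89 and Fbxo32 at 0.75. Lysosome and autophagy genes fell in 8 of 29 cases and rose in 1 (median -0.18, 10 and 2 adjusted over the list alone, adjusted p = 0.00966, but 0.389 with an estimated correlation), with the lysosomal hydrolases Glb1 at -1.08 and Neu1 at -0.88, and the list's median was -0.11 without vehicle library 2. Inflammatory genes rose in 4 of 20 cases (median 0.95, 12 adjusted over the list alone) and neutrophil markers in 2 of 8 (1.36, 3 adjusted over the list alone), with adjusted p = 0.384 and 0.389 with an estimated correlation. The inflammatory median was 0.56 without castration + AZD2014 library 2 and the neutrophil median 2.43 without vehicle library 3.

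Pten (0.22), Ar (0.19), Nr3c1 (0.34), Mtor (0.08), Rptor (-0.08) and Rictor (0.66) did not pass by edgeR between castration + AZD2014 and vehicle, and voom called Nr3c1 (0.52). Groups did not overlap for 1479 genes (10.7%, where chance gives 1.59%). The count of 1968 was 1269 without vehicle library 1, 3130 without vehicle library 3, 1155 and 1160 without castration + AZD2014 libraries 1 and 3, 897 without vehicle libraries 1 and 5, and 1013 with only the groups compared.

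Castration + AZD2014 against castration asked what the drug added in castrated animals. Interferon response genes were higher as a list in the castration + AZD2014 tumours, with a median log2 fold change of 1.79, while no single gene passed by edgeR. The adjusted p of this list was 1.84e-30 at the preset correlation, with 21 of 25 genes higher when adjusted over the list alone and 0 over all genes tested, but 0.269 with an estimated correlation. All 4 castration + AZD2014 libraries had an interferon score above the castration mean, and the 2 groups overlapped (0.68 to 2.42 against -1.26 to 0.71). Of all genes the interferon-induced Oasl1 (ENSMUSG00000041827, chromosome 5, 114923240 to 114937915) had the smallest p, at 16.9 ± 7.72 CPM after castration and 100 ± 62.6 CPM after castration + AZD2014 (SD, n = 4 each; log2 2.57 ± 0.47, adjusted p = 0.207).

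By edgeR 0 genes were called, 1522 had an unadjusted p below 0.05 where 689 would by chance, and DESeq2 called 105 and voom 121. The other genes of smallest p by edgeR, none called by it, were Oas1g (1.76) and Pla2g4c (1.49) among those higher, and Tpcn1 (-0.60), Ddit4 (-0.88) and Dhrs11 (-0.57) among those lower. DESeq2 and voom both called Oasl1, Oas1g, Tpcn1 and Ddit4, while only DESeq2 called Dhrs11 and only voom Pla2g4c, and the fit with a replicate block called Oasl1. Interferon list members of smallest p were Oas1a (1.5), Mx1 (2.62), Mx2 (2.54) and Tap1 (1.01), all called by DESeq2 and by voom but not by edgeR. Without castration + AZD2014 library 4, edgeR called 8 genes, among them Oasl1 (2.77) and Oas1g (1.97). Groups did not overlap for 506 genes (3.7%, where chance gives 2.86%).

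The oxidative phosphorylation (median -0.48, adjusted p = 1.60e-16), ribosomal protein (-0.25, adjusted p = 6.90e-08), ATF4 (-0.19, adjusted p = 9.45e-05) and sterol synthesis lists (-0.27, adjusted p = 0.000552) passed as lower, and FoxO targets as higher (0.25, adjusted p = 0.00219). With an estimated correlation the adjusted p was 0.588 for 4 of them and 0.792 for ribosomal proteins. Each of these 5 had 0 members called over all genes, and 0, 0, 3, 1 and 0 adjusted over the list alone. Castration + AZD2014 libraries 1 and 3 carried the oxidative phosphorylation difference (scores -0.61 and -0.68), and libraries 2 and 4 (-0.10 and -0.09) lay within the castration range of -0.22 to 0.29. Ribosomal protein scores were -0.42 and -0.31 in libraries 1 and 3 and 0.11 and 0.25 in libraries 2 and 4, against -0.12 to 0.43 after castration. Oxidative phosphorylation and ribosomal protein scores were also both lowest in library 3 among vehicle (-0.24 and -0.32) and among AZD2014 libraries (-0.29 and -0.25). These lists thus varied together in intact animals too and are not independent results. The ribosomal protein median was -0.14 without castration library 1 and -0.13 without castration + AZD2014 library 1. The sterol synthesis median was -0.15 without castration library 1 and the FoxO median 0.15 without castration + AZD2014 library 3. Members of smallest p were Cycs (cytochrome c) at -0.64, Aars at -0.41, Insig1 at -0.67 and Fbxo32 at 0.53, none of them called by edgeR, though DESeq2 called Aars and Insig1 and voom Aars. Red blood cell genes passed as lower (median -1.24, 0 of 5 called, 4 adjusted over the list alone, adjusted p = 0.00219, but 0.588 with an estimated correlation), though not with voom (-0.67), and their median was -0.75 without castration library 1. Pten (0.23), Ar (-0.03), Nr3c1 (0.18), Mtor (0.15), Rptor (-0.06) and Rictor (0.54) were not called.

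Castration + AZD2014 against AZD2014 asked what castration changed in drug-treated tumours. Most macrophage, interferon, neutrophil and basal epithelium genes rose, and most prostate secretory genes fell. Cxcl13 (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068) rose from 2.10 ± 0.488 CPM (SD, n = 5) to 60.1 ± 22.0 CPM (SD, n = 4), a log2 fold change of 4.83 ± 0.53 (SE, adjusted p = 2.66e-05). Lyz2 rose from 137 ± 33.4 to 731 ± 110 CPM (SD, n = 5 and 4; log2 2.42 ± 0.25, adjusted p = 2.03e-05). With 1882 genes higher and 1572 lower, 1499 of them by more than 2-fold, this comparison had the most calls of the 5.

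Myh15 had 94 counts in the castration + AZD2014 group and 0 in the AZD2014 group, at least 36.4-fold higher against a floor of 3 counts over the group. Ccdc190 rose from 2 to 144 counts, a ratio of 83.8 (counting interval 22.8 to 698). Gabrg3 (5.42), Chil1 (5), Cxcl13 and Cdhr1 (4.74) were the other largest rises among genes whose groups did not overlap, and Chil1 did not pass without castration + AZD2014 library 2 (3.25), with voom (3.64) or with a replicate block (4.15). In the opposite direction, 9530002B09Rik was at least 399-fold and Sbp at least 78.5-fold lower, and Msmb (-9.04), Mup20 (-8.32), Spink5 (-7.98) and 5430419D17Rik (-7.60) fell, of which Msmb (-8.59), Mup20 (-8.10) and Spink5 (-8.20) were not called with voom.

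Macrophage markers rose in 10 of 11 cases (median 1.58, 10 higher and 1 lower adjusted over the list alone, adjusted p = 3.58e-15, but 0.074 with an estimated correlation), with C1qb at 1.62. Interferon genes rose in 21 of 25 cases (median 1.67, 24 adjusted over the list alone, adjusted p = 1.97e-10, but 0.386 with an estimated correlation), with Zbp1, a sensor of nucleic acids, at 2.56 and Gbp2 at 2.55, and the median was 1.01 without castration + AZD2014 library 3. Basal epithelium markers rose in 7 of 11 cases (median 2.18, 10 adjusted over the list alone, adjusted p = 1.89e-06, but 0.328 with an estimated correlation), with the basal keratins Krt14 at 2.60 and Krt5 at 2.31. Neutrophil markers rose in 7 of 8 cases (median 2.93, 8 adjusted over the list alone, adjusted p = 2.11e-05, but 0.328 with an estimated correlation). T and NK markers rose in 9 of 11 cases (1.76, 10 adjusted over the list alone, adjusted p = 8.55e-06, but 0.328 with an estimated correlation). Inflammatory genes rose in 10 of 20 cases, with 1 lower (1.5, 17 and 1 adjusted over the list alone, adjusted p = 2.11e-05, but 0.386 with an estimated correlation). Examples were S100a8 at 3.20, Csf3r at 2.88, Gzmb at 2.33, Nkg7 at 1.77, the monocyte chemokine gene Ccl2 at 2.91 and Il1rn at 2.46. Without castration + AZD2014 library 2 the inflammatory median was 0.99. In these 6 list scores the 4 castration + AZD2014 libraries lay above all 5 AZD2014 libraries.

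Prostate secretory genes fell in 8 of 10 cases (median -4.66, also at the bound, 8 adjusted over the list alone, adjusted p = 2.90e-06, but 0.177 with an estimated correlation), with Azgp1 at -4.01. Oxidative phosphorylation genes fell in 10 of 35 cases (median -0.45, 19 adjusted over the list alone, adjusted p = 3.29e-06, but 0.733 with an estimated correlation), with Sdha at -0.58 and Atp5a1 at -0.53. Here too only castration + AZD2014 libraries 1 and 3 (scores -0.61 and -0.68) lay below the AZD2014 range of -0.29 to 0.37. Cell cycle genes rose in 13 of 31 cases (median 1.12, 15 adjusted over the list alone, adjusted p = 3.91e-05, but 0.733 with an estimated correlation), with Ccne1 at 1.38 and E2f1 at 1.23, neither of them called without castration + AZD2014 library 2 (1.09 and 0.88), where the list's median was 0.69. Cell cycle scores of castration + AZD2014 libraries 1 and 2 (0.51 and 0.85) lay above the AZD2014 range of -1.22 to -0.22. Those of libraries 3 and 4 (-0.51 and -0.74) lay within it. Ribosome biogenesis genes rose in 9 of 28 cases (median 0.23, 10 higher and 1 lower adjusted over the list alone, adjusted p = 0.000467, but 0.328 with an estimated correlation), with Heatr1 at 0.90 and Nolc1 at 0.86 ± 0.09. Neuroendocrine markers rose in 4 of 12 cases (median 1.56, 4 adjusted over the list alone, adjusted p = 0.00618, but 0.733 with an estimated correlation), with Ascl1 at 2.12 and Eno2 at 1.73. This list did not pass without castration + AZD2014 library 4 (0.62). Ar (-0.54 ± 0.19, adjusted p = 0.0488) was called here but only 5 of the 18 fits without 1 library kept the call (those without vehicle library 3 or 4, AZD2014 library 5, castration library 1 or castration + AZD2014 library 3), and over the other 13 it ran from -0.59 to -0.42. Pten (-0.32), Nr3c1 (0.26), Mtor (-0.01), Rptor (-0.23) and Rictor (0.14) did not pass. Groups did not overlap for 2987 genes (21.7%, where chance gives 1.59%).

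**Figure D2:**
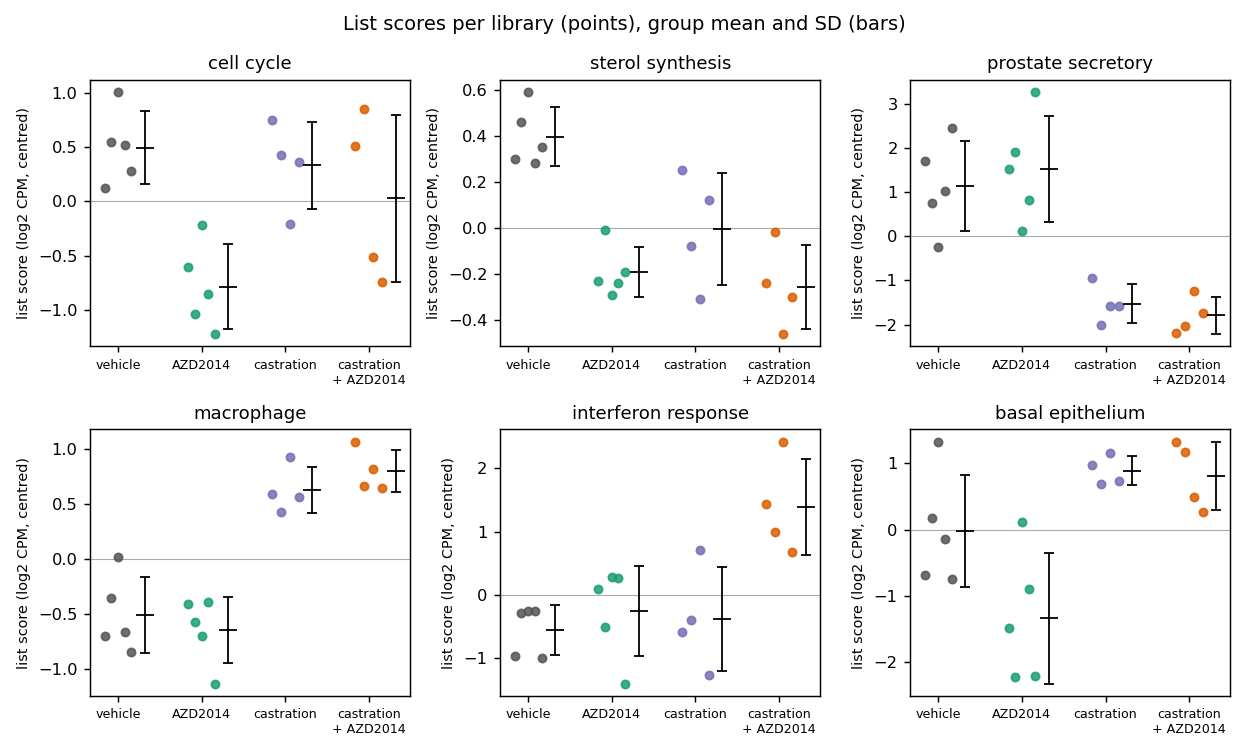
List score of each library (points; mean over list members of log2 CPM centred on each gene's mean over the 18 libraries) in the 4 groups for 6 gene lists, with the group mean and SD as bars. Prostate secretory scores of the 8 castrated libraries (-2.18 to -0.94) lie below those of the 10 intact ones (-0.25 to 3.27), while cell cycle scores were lower with AZD2014 in intact animals (-1.22 to -0.22 against 0.12 to 1.01 with vehicle).

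Most genes called for castration without the drug moved the same way with it. Of the 863 genes called for castration without AZD2014, 813 (94.2%) had the same sign with it, and across these genes the fold changes correlated at r = 0.91 (0.45 over all 13777 genes, Spearman rho 0.42). The 2 castration comparisons share no library. They shared 286 higher genes, where independence would give 50.5, and 348 lower genes, where it would give 56.3, and 4 genes were called in opposite directions. The castration effects were not alike throughout: the cell cycle list had a median of -0.12 with 0 of 31 genes called without AZD2014 and of 1.12 with 13 called with it. Only castration + AZD2014 libraries 1 and 2 (scores 0.51 and 0.85) lay above the AZD2014 range, and libraries 3 and 4 (-0.51 and -0.74) within it. The interaction of the cell cycle list passed at the preset correlation (adjusted p = 5.56e-09, but 0.723 with an estimated correlation). Correlations here are across genes, which are not independent replicates.

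The effect of AZD2014 was compared between intact and castrated animals, again with no library in common. Across all genes the fold changes correlated at r = -0.09 (Spearman rho 0.13). Of the 1916 genes called in intact animals, 72.4% had the same sign in castrated animals, with a median of 0.63 without regard to sign in intact and of 0.12 in the same direction in castrated animals. Pearson's r was 0.02 without vehicle library 3, -0.25 without castration library 1, 0.00 without castration + AZD2014 library 3 and -0.16 without castration + AZD2014 library 4. It was also -0.15 without AZD2014 library 3, -0.05 without AZD2014 library 5 or castration library 4 and -0.03 without castration + AZD2014 library 2.

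**Figure D3:**
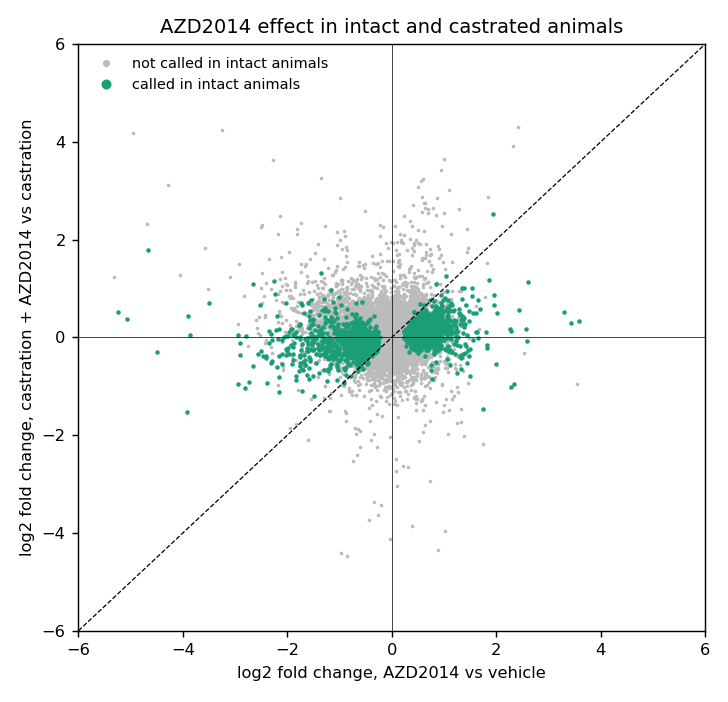
Log2 fold change of AZD2014 in castrated animals (vertical) against that in intact animals (horizontal) for 13766 genes (11 lie outside the axes), with genes called in intact animals in green and the line of equal effects dashed. Green points, picked by their call in intact animals, have a median absolute change of 0.63 there and a median change in the same direction of 0.12 in castrated animals.

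The interaction between castration and AZD2014 tested this difference gene by gene and passed for 40 genes, 25 with a more positive and 15 with a more negative drug effect in castrated animals. Linker histone genes were among those of smallest p: H1f0 was at 172 ± 16.5 CPM with vehicle, 453 ± 43.6 with AZD2014, 183 ± 7.50 after castration and 222 ± 35.5 after castration + AZD2014 (SD, n = 5, 5, 4 and 4; interaction -1.12 ± 0.16, adjusted p = 0.00929). Hist1h1c had an interaction of -1.88 ± 0.28 (adjusted p = 0.00929). Aen, a p53-induced nuclease gene, was at 52.2 ± 3.76 CPM with vehicle, 17 ± 1.98 with AZD2014, 47.7 ± 8.66 after castration and 39.3 ± 6.92 after castration + AZD2014 (interaction 1.34 ± 0.19, adjusted p = 0.00929). Mphosph10, of the rRNA processing complex, followed at 1.47 ± 0.22 (adjusted p = 0.00929), with Nolc1 at 0.76 and the surface antigen gene Tacstd2 at 0.79 (adjusted p = 0.0214 each). Nolc1 did not pass without castration library 4 (0.75) or castration + AZD2014 library 2 (0.69), nor Tacstd2 without castration library 3 (0.77) or 4 (0.80). Pten (-0.31), Ar (-0.76), Nr3c1 (0.10), Mtor (0.06), Rptor (-0.20) and Rictor (0.01) did not pass.

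As lists, interferon (median interaction 1.47, adjusted p = 1.75e-09), cell cycle (1.16, adjusted p = 5.56e-09), basal epithelium (1.25, adjusted p = 0.000904), sterol synthesis (0.36, adjusted p = 0.00175) and neutrophil genes (1.81, adjusted p = 0.00529) had a more positive drug effect in castrated animals. Oxidative phosphorylation (-0.39, adjusted p = 1.09e-05) and ribosomal protein genes (-0.29, adjusted p = 1.26e-05) had a more negative one. Of their members 1 passed over all genes, in sterol synthesis, and 2 there and 1 in the cell cycle list adjusted over the list alone, and with an estimated correlation none of the lists passed (adjusted p = 0.723 for each of these 7). Without vehicle library 3 the neutrophil median was 0.84 (its neutrophil score was 1.62 against -1.54 to -0.22 in the other vehicle libraries) and the basal epithelium median 0.83. The cell cycle median was 0.75 without castration + AZD2014 library 2, and the ribosomal protein median was -0.14 without AZD2014 library 5, -0.17 without castration library 1 and -0.19 without castration + AZD2014 library 1. The count of 40 was 24 without AZD2014 library 1 or 2, 23, 5 and 4 without castration libraries 2, 3 and 4, and 6, 5 and 126 without castration + AZD2014 libraries 1, 2 and 4.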

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

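The fits without vehicle libraries 1 and 5, the thinned fits, the held-out intact libraries, the macrophage and T cell covariates, the splits of the interferon score and the seminal vesicle tests were chosen after the results were seen.

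AZD2014 changed 1916 genes in intact animals and 0 in castrated animals by edgeR (1522 at an unadjusted p below 0.05, 105 by DESeq2, 121 by voom), and 40 genes passed the interaction itself. Lower depth and fewer libraries do not account for the difference: with 4 libraries a group thinned to the depths of the castrated groups, at least 914 genes were still called in intact animals over 25 fits. An equal effect that the test missed in castrated animals was looked for with held-out libraries. Genes picked in 2 against 2 intact libraries moved as far in castrated groups as in the held-out intact libraries in 1 of 100 splits. The median was 0.55 in held-out intact libraries against 0.14 in castrated groups, with 92.8% and 70.4% of the same sign. The measured change was thus smaller in these castrated animals. All splits reuse the same libraries, so the share leaves out the spread between castrated animals. It is not a p-value and cannot decide whether an equal effect was missed. Seminal vesicle transcripts in vehicle libraries 1 and 5 could not produce the intact effect alone, since 1263 genes were called without them. The biological explanation, a drug effect that depends on castration, was tested directly by the interaction alone.

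Other splits of the libraries into groups of the same sizes were tested for each count of called genes. At least as many genes as the real grouping were called in 1 of 100 splits for AZD2014 against vehicle (highest other 1), in 2 of 100 for castration against vehicle (1594), in 2 of 100 for castration + AZD2014 against vehicle (2966), in 1 of 100 for castration + AZD2014 against AZD2014 (1602) and in 2 of 100 of the 8820 possible for the interaction (630). These shares are below 0.05, but in 3 of the 5 another split gave more genes than the real grouping. The median of the other splits was 0 genes in each of the 5. For the interaction, the splits exchanged libraries with and without the drug. The exchange was made separately in intact and castrated animals, so a drug effect common to both can enter the interaction of a split. That share therefore does not test the interaction alone. For castration + AZD2014 against castration, 35 of 35 splits gave at least the real count, which decides nothing since that count was 0 (highest other 4). The highest other split called several times the real count for the interaction, which points to a structure of the samples. Vehicle library 3 was out of its group in the highest split for castration against vehicle (set with castration libraries), for castration + AZD2014 against vehicle (exchanged with castration + AZD2014 library 4) and, with 7 other libraries, for the interaction.

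Interferon genes were higher as a list in castration + AZD2014 than in castration (median 1.79) at the preset correlation, but not with an estimated one (adjusted p = 0.269). More macrophages and T cells in the tumours are disfavoured as the whole cause, since the median was 1.59 with macrophage and T and NK scores as covariates (0 genes called). A single library does not carry it either, with a lowest median of 1.38, without castration + AZD2014 library 3, over the 18 fits that leave out 1 library. Spread between animals remains possible: 2 of 35 splits of the 8 castrated libraries had at least as large a difference of the score as the real 1.77 (exact two-sided p = 0.0571, where the smallest possible is 0.0286).

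Seminal vesicle genes were high in vehicle libraries 1 and 5: in vehicle library 1, 6 of 6 tested genes passed 100 CPM while staying under it in the other 8 intact libraries, which fits seminal vesicle tissue in the sample. In vehicle library 5 only 4 of 6 did, with Svs1 at 3.60 and Svs6 at 7.67 CPM against 5340 and 9560 in vehicle library 1, so the source may be tissue or not. Vehicle library 5 also had the highest vehicle scores for smooth muscle (4.29, others at most 0.98), skeletal muscle (2.49, at most 0.51), adipocyte (3.44, at most 0.59) and urothelium genes (2.28, at most 0.52). A stronger androgen response of the tumour could not be told apart: the highest seminal vesicle score was -0.35 among other intact libraries with a secretory score above 1.71, but these were only AZD2014 libraries 2 and 5. Vehicle libraries 1 and 5 had the highest secretory scores (1.71 and 2.44) but the lowest androgen target scores (0.10 and -0.02, against 0.19 to 0.30) of the vehicle group, so these values point both ways.

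A library was set apart where its distance to the nearest other library of its group was a large share of the group's range, at a limit that chance passes in about 1 of 20 groups. Of 412 groups of values, 23 had such a library (19 of 292 for genes, 3 of 100 for lists, 1 of 20 for library measures), which is close to the share that chance gives. In vehicle library 3 this held for Ccdc190 (share 0.809; 1.21 CPM against at most 0.132), Nuf2 (0.792; 6.90 against 3.01 to 3.60), Nr3c1 (0.75; 29.5 against 18.5 to 20.8), Mtor (0.742; 52.8 against 38.9 to 42.1), Krt13 (0.712; 14.0 against 0.626 to 1.85), Glb1 (0.712; 119 against 195 to 238) and Uqcrfs1 (0.712; 118 against 160 to 181). In vehicle library 5 it held for Pfkfb3 (0.792; 288 against 25.9 to 42.9) and Lpo (0.783; 300 against 0.264 to 2.30).

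In AZD2014 library 5 it held for Mtor (0.787; 37.0 CPM against 46.9 to 50.0), Il1rn (0.774; 8.80 against 19.5 to 24.5), Hist1h1c (0.757; 1350 against 719 to 838), Pcna (0.738; 22.1 against 28.1 to 30.6) and the gene total (0.712; 4877760 against at least 7181024 counts). It also held for Lpo in AZD2014 library 2 (share 1; 0.146 CPM against 0), Msmo1 in AZD2014 library 3 (0.83; 17.4 against 20.1 to 20.7), Cd3g in castration library 3 (0.898; 19.4 against 9.89 to 10.6), Sbp in castration library 4 (share 1; 0.135 against 0), and Msmo1 (0.925; 31.4 against 23.8 to 24.3) and S100a8 (0.907; 62.2 against 26.9 to 29.1) in castration + AZD2014 library 2. Among list scores it held for fibroblast genes in castration library 4 (0.855; -0.85 against -0.14 to -0.02), immediate early genes in AZD2014 library 3 (0.754; 0.62 against 0.01 to 0.16) and seminal vesicle genes in castration library 1 (0.872; 1.72 against -1.80 to -1.35). The share of 1 for Lpo and for Sbp was fixed in advance, since a single count made up the whole group's total. Reads ambiguous between genes were 0.66% of lines in castration and in castration + AZD2014, where vehicle reached at most 0.62%.

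Differences between groups in the effect of AZD2014 passed for 40 genes, with interactions of -1.12 for H1f0, 1.34 for Aen, -1.88 for Hist1h1c, 1.47 for Mphosph10, 0.76 for Nolc1 and 0.79 for Tacstd2. Lists that passed with the preset correlation had medians of 1.47 (interferon), 1.16 (cell cycle), -0.39 (oxidative phosphorylation), -0.29 (ribosomal proteins), 2.24 (fibroblast), 1.25 (basal epithelium), 0.36 (sterol synthesis), 2.95 (smooth muscle), -3.36 (adipocyte), 1.81 (neutrophil), 0.32 (glycolysis), 0.09 (ribosome biogenesis), -0.09 (FoxO targets), 0.56 (inflammatory) and 13.82 (seminal vesicle). With an estimated correlation none of these 15 passed (adjusted p = 0.723 for each).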

How the results depend on the processing

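The fits without vehicle libraries 1 and 5 and the thinned fits were chosen after the results were seen. Of 11293 gene values under alternatives, 10871 (96.3%) kept their side of the threshold, 260 were no longer called and 162 were newly called. These cover only named genes and leading members of called lists, at most 407 a fit, with 200 called in the main fit. No such gene called in the main or the alternative fit reversed, and the direction of those called in neither was not checked. Many of these genes were picked as large changes, so the 96.3% does not describe all calls. Of all 863 calls for castration against vehicle, 846 were kept with DESeq2 size factors and 349 with only the groups compared. For castration + AZD2014 against vehicle, 1957 of 1968 were kept with those size factors and 813 without vehicle libraries 1 and 5. Of 2226 list values 2032 (91.3%) kept their direction and their call and 4 reversed. The cause of the changes below was not tested. Lists have no value with DESeq2, nor the interaction with only the groups compared. Genes called for AZD2014 against vehicle (1916) numbered 1328 to 2017 without 1 library, 3197 with voom, 1263 without vehicle libraries 1 and 5, and at least 914 with 4 thinned libraries a group. For castration against vehicle (863) they were 407 to 1598 without 1 library, 363 with only the groups compared, 2437 with voom and 434 without vehicle libraries 1 and 5. For castration + AZD2014 against vehicle (1968) they were 1155 to 3130, 1013, 4025 and 897 in the same order. Castration + AZD2014 against castration (0) gave 0 to 8 without 1 library, 105 with DESeq2, 121 with voom and 1 with a replicate block, and castration + AZD2014 against AZD2014 (3454) gave 2334 to 3899. The interaction (40) gave 4 to 126 without 1 library, 281 with DESeq2, 229 with voom and 23 with a replicate block. Lists called (8, 14, 18, 14, 11 and 15 in the order above) were 0, 3, 1, 0, 0 and 0 with an estimated correlation. The correlation of drug effects (-0.09) ran from -0.25 to 0.02 without 1 library. The 4 reversed values were the fibroblast list in AZD2014 against vehicle with voom (0.09 against -1.48), the cell cycle list in castration + AZD2014 against castration without castration + AZD2014 library 3 (0.03) or 4 (0.06; -0.18 with all, -0.45 to 0.06 without 1 library), and the FoxO list in the interaction without AZD2014 library 3 (0.00; -0.09 with all, -0.24 to 0.00 without 1 library). What depth alone limits was not measured, since the thinned fits also had fewer libraries and the simulation kept the depth as it was.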

Other observations

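The histone family was singled out, and the fits without vehicle libraries 1 and 5 were chosen, after the results were seen. Of 15 tested Hist genes, all 15 were higher with AZD2014 in intact animals and 13 were called (median 1.81; 12 called with DESeq2, 14 with voom). In castrated animals the drug gave a median of 0.27 with 0 called, and the interaction had a median of -1.52 with 4 called. Castration alone gave -0.01 with 0 called, castration + AZD2014 against vehicle 0.24 with 1 called, and castration + AZD2014 against AZD2014 -1.78 with 12 lower.

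The list calls in this paragraph all ended with an estimated correlation (adjusted p of 0.588 to 0.792). Immediate early genes were higher in castration + AZD2014 than in castration (median 0.35, 0 of 16 called), a call that ended without castration library 2 (0.30). Adipocyte genes were lower in the same comparison (-3.64), but not without castration library 1 (-1.15) or with voom (-0.97), and their interaction (-3.36) also ended without that library (-0.74), with -5.54 without vehicle library 5. Smooth muscle genes (1.19) ended without castration library 2 (1.24) or 4 (1.01) or castration + AZD2014 library 3 (0.86) or 4 (1.40). Glycolysis genes (-0.19) ended without castration library 1 (-0.14) or 3 (-0.16) or castration + AZD2014 library 2 (-0.18) or 4 (-0.22), and ribosome biogenesis (-0.13) without castration library 1 (-0.07) or castration + AZD2014 library 4 (-0.11). Cell cycle genes (-0.18) ended without castration library 1 (-0.03) or 2 (-0.17) or castration + AZD2014 library 3 (0.03) or 4 (0.06), with -0.31 without castration library 3 and -0.28 and -0.45 without castration + AZD2014 libraries 1 and 2, and lysosome genes (-0.06) without vehicle library 2 (-0.05) or 5 (-0.06), castration library 3 (-0.02) or 4 (-0.05), or castration + AZD2014 library 1 (-0.04), 2 or 4 (-0.09 each).

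The list calls in this paragraph also ended with an estimated correlation (adjusted p of 0.384 to 0.793). In castration against vehicle, fatty acid synthesis genes (-0.30) ended without vehicle library 3 (-0.29) or 5 (-0.19) or castration library 3 (-0.26), and ribosomal proteins (0.24) without vehicle library 3 (0.17), with 0.13 without castration library 1. Ribosome biogenesis (0.12) ended without castration library 1 (0.09) or 4 (0.11), fibroblast genes (-1.54) without vehicle library 3 (-0.63) or 5 (-1.51) or castration library 4 (-1.34), and neuroendocrine genes (0.44) without vehicle library 2 (0.29) or 3 (0.34), with 1.35 without vehicle library 5. In castration + AZD2014 against vehicle, fatty acid synthesis (-0.25) ended without vehicle library 3 or 5 (-0.23 each), glycolysis (-0.37) without vehicle library 2 (-0.11), and the cell cycle list (-0.37) without vehicle library 3 (-0.17) or castration + AZD2014 library 3 (-0.17) or 4 (-0.14), with -0.71 without castration + AZD2014 library 2. Basal epithelium (0.65) ended without vehicle library 1 (0.56) or 5 (0.55) or castration + AZD2014 library 1 (0.54) or 2 (0.48), with 1.23 without vehicle library 3, and neuroendocrine genes (0.61) without vehicle library 2 (0.48), 3 (0.49) or 4 (0.46), AZD2014 library 3 (0.63) or castration + AZD2014 library 4 (0.24), with 1.82 without vehicle library 5 and 0.95 without castration + AZD2014 library 1. Red blood cell genes were lower there (-1.45), though not without vehicle libraries 1 and 5 (-1.04).

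With an estimated correlation none of the interaction lists passed (adjusted p = 0.723 for each list below). In the interaction, smooth muscle genes (2.95) ended without vehicle library 5 (1.04) and glycolysis (0.32) without vehicle library 2 (0.15) or castration library 2 (0.28), with 0.50 without vehicle library 5. Ribosome biogenesis (0.09) ended without AZD2014 library 1 (0.07), 3 (0.14) or 4 (0.10), castration library 2 (0.12) or castration + AZD2014 library 2 (0.07), and over all 18 fits it ran from 0.05 (without vehicle library 3) to 0.15 (without vehicle library 5 or AZD2014 library 5). FoxO targets (-0.09) ended without vehicle library 1 (-0.09) or 5 (-0.04), AZD2014 library 3 (0.00) or 4 (-0.13), castration library 2 (-0.11), or castration + AZD2014 library 2 (-0.04) or 4 (-0.11), and the lowest value was -0.24 (without vehicle library 2). Inflammatory genes (0.56) ended without vehicle library 2 (0.53) or 3 (0.09), AZD2014 library 3 (0.67) or 5 (0.55), castration library 2 (0.45) or 3 (0.31), or castration + AZD2014 library 2 (0.18), with 0.91 without castration library 1. Seminal vesicle genes (13.82) ended without vehicle library 1 (12.04) or 5 (12.60), castration library 1 (15.59), 2 (12.88), 3 (12.90) or 4 (12.88), or castration + AZD2014 library 4 (13.71), and the median was 8.41 without castration + AZD2014 library 3 and 2.69 without vehicle libraries 1 and 5. Fibroblast genes (2.24) were not called with voom (0.98), with 1.15 without vehicle library 3.

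Luminal progenitor, luminal epithelium, B and plasma cell, endothelium, skeletal muscle and urothelium lists passed in no comparison. Their medians for AZD2014 against vehicle were -0.31, 0.03, 0.06, -0.28, -0.94 and -0.07, and for castration against vehicle -0.07, -0.07, 0.78, -0.14, -0.22 and -0.48. Luminal progenitor scores after castration (-0.37 to -0.02) and castration + AZD2014 (-0.58 to -0.14) nevertheless lay below all vehicle scores (0.17 to 0.8). The mean log2 fold changes of this list against vehicle were -0.6 and -0.71. For AZD2014 against vehicle the mean had the opposite sign to the median in luminal epithelium (-0.04) and in B and plasma cells (-0.17), and the urothelium test pointed up. The gene Gm42418 held 2.38% of counts in vehicle library 3 (95% Wilson interval 2.374% to 2.395%) and 3.72% in castration library 1 (3.698% to 3.735%), and 0.209% (0.2058% to 0.212%, vehicle library 4) to 1.07% (1.056% to 1.074%, AZD2014 library 5) in the others.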
